A study of Homo sapiens with 54 samples.

How the data were processed

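The 54 samples were cultures of primary human airway smooth muscle cells grown from the tracheas of 4 donors and used at passage 5 to 8. Per the labels' protocols, the cells stably expressed either green fluorescent protein (GFP), as the control, or PKI-GFP, a fusion of that protein with the peptide inhibitor of the cAMP-dependent protein kinase (PKA). They were held without serum for 24 h, pretreated for 30 min with vehicle or with 10 nM fluticasone propionate, an inhaled glucocorticoid, and stimulated for 8 h with 20 U/ml interleukin-1beta (IL-1beta), 10 nM epidermal growth factor (EGF), both, or neither. The labels give the pretreatment time of the arrays with fluticasone alone, and their total exposure is not given in the sources used here. Total RNA (5 ug) was turned into biotinylated cRNA and hybridised to 1 Affymetrix array per sample.

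The authors deposited a table of log2 values per probe set, normalized with GCRMA per the submitters' processing notes. GCRMA subtracts a background modelled from probe sequence, normalizes the arrays to a common distribution and summarises each probe set. Its version, its settings and whether all arrays were processed together are not given in the sources used here. Values near the bottom of such a scale are mostly background, so a change from a silent level is compressed, and the table holds no detection calls. The array medians over all probe sets ran from 3.299 to 3.49 on the log2 scale. Arrays carry no read depth, and their number is what limits the precision.

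The table held 22283 probe sets, of which 68 were control probe sets and were left out of the gene tests. Of the others, 19065 had 1 gene symbol in the platform annotation and 1043 had several, while 2107 were unnamed there. Symbols were looked up by Entrez ID in a gene table of the GRCh38.p14 assembly, which matched 19053 probe sets and changed 0 symbols, and 12 kept the annotation's symbol. Probe sets with several symbols or none were not analysed here, so genes seen only by such probe sets are absent from the lists below. For each gene, the probe set with the highest mean over all arrays was used. Of 11963 genes, the 7693 whose value lay above the array's median over all probe sets on at least 3 arrays were tested.

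Groups were taken from the sample titles. There were 16 groups of 3 or 4 arrays, since donor 1 was used only without fluticasone and without IL-1beta given alone. The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), fitted once to all 54 arrays as 16 group means with 38 residual degrees of freedom, so that all groups shared 1 estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over the genes of each of the 18 contrasts, and a gene was called at an adjusted p under 0.05. Changes are log2 differences with limma's moderated standard error (written ± SE). The comparisons, the tests, the gene lists, the rule for naming genes and the main alternatives were fixed before the data were examined.

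The replicate number in the titles is the donor, so the numbers pair the arrays. Over 375 pairs of arrays of 1 donor in different groups, the deviations from the group means correlated with a median of 0.558 (lowest -0.0995), against a median of -0.211 over 990 pairs of different donors. Of the 54 arrays, 53 correlated best with their own donor's arrays, and 1 did not match its donor label. A fit with donor as a block (35 residual degrees of freedom) was the main alternative. Its count stands beside each count of a contrast or an overlap that it moved by over 1.5 times. For members of gene lists it is given only in some places, and other list counts moved as much. No same-group pair of arrays held identical values. Over the tested genes such pairs correlated with a median r of 0.9489, from 0.8546 to 0.9865, and the highest pair held the array that did not match its donor label.

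Shifts of 21 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 342 pairs of contrast and list with at least 3 tested members, and again with an estimated correlation. Of these pairs, 77 passed with the preset and 23 with the estimated correlation, all 23 in the same direction, and 77 passed with donor as a block. Beside the calls of a list over all genes, calls adjusted over the list alone are given where a list is counted. Genes were named by rule: the first 10 higher and the first 10 lower genes by size of change among those called with the same direction in every donor that has all arrays of the contrast; up to 4 members per list and contrast with the smallest adjusted p, or the member with the largest change where none passed; and PTGS2, IL6, CXCL8, FKBP5, TSC22D3, DUSP1, CREM, NR4A2, PKIA and NR3C1. Sex-linked marker genes were left out. For 4 overlaps of called genes, the count expected of independent lists is given, and the shared control arrays were also split 2 and 2. In 20 simulations of unchanged groups the mean overlap was 0 for all 4, whatever was observed, and nothing rests on them.

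The alternatives were the donor block, no filter on dim probe sets, a filter at the 60th percentile of mean signal, quantile normalization between arrays, the mean of a gene's probe sets, eBayes without a trend, a fit on the compared groups alone, and leaving out each donor in turn. Chosen after seeing the data were fits without the array that matched another donor, without the 4 EGF arrays of replicate 3, and with the 3'/5' log ratio of the actin control probe sets as a covariate, and a test of PKI on 1 value per donor. Labels were reassigned in up to 100 ways per contrast, and for the mean PKI effect also by whole transduced cultures.

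The procedure was tested on simulated data with the real layout, gene means and spreads, and 200 changed genes among 7693. For IL-1beta against basal it recovered 46.3% of the genes changed by 1 log2 unit, 73.1% of those changed by 2 and 100% of those changed by 4. For EGF with IL-1beta against basal the shares were 38.8%, 88.1% and 97%. For the mean PKI effect they were 92.5%, 100% and 100%, and for the interaction of PKI with EGF plus IL-1beta 23.9%, 62.7% and 89.4%. The simulated errors were independent between arrays, with no shared donor or culture. The shares therefore do not cover that dependence, which the real arrays have. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.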

Results

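Transcript levels were measured with arrays that gave 11963 genes here, in human airway smooth muscle cells. These are the contractile cells of the airway wall, which also secrete inflammatory mediators. Control cells (GFP) and cells with a PKA inhibitor (PKI) were each given no stimulus (basal), IL-1beta, EGF, or EGF with IL-1beta, with or without fluticasone. The groups without fluticasone held 4 arrays each, except the IL-1beta groups with 3, and the groups with fluticasone held 3 arrays each, in GFP and in PKI cells alike. All 54 arrays came from 4 donors, so p-values treat arrays as independent that share a donor, and the fit with donor as a block stands beside the main counts. The comparisons address how a cytokine and a growth factor act on these cells alone and together, what a glucocorticoid takes away from that response, and how much of it depends on PKA.

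**Figure D1:**
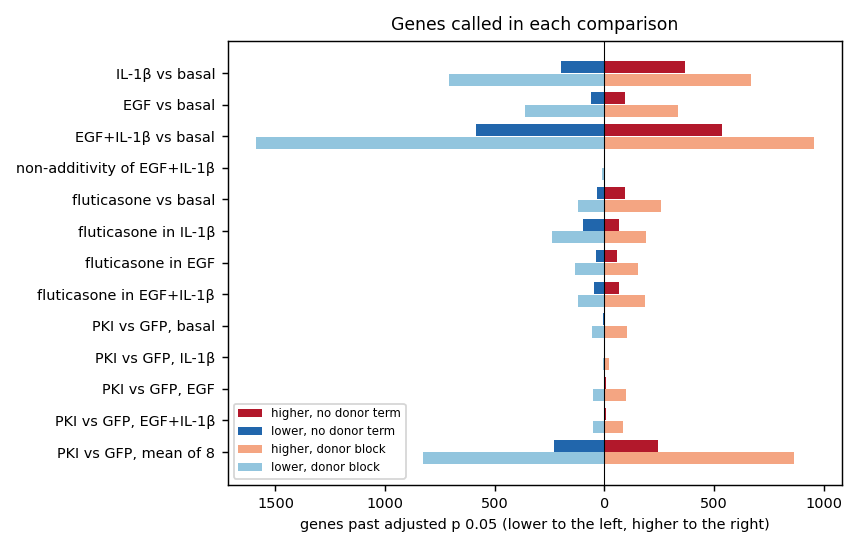
Number of genes past an adjusted p of 0.05 in 13 comparisons, lower to the left and higher to the right of 0. Dark bars are the fit without a donor term and light bars the fit with donor as a block. EGF with IL-1beta against basal has the longest dark bars (536 higher, 585 lower).

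IL-1beta set off a broad secretory and antiviral-type program in control cells. The neutrophil chemokines CXCL2 (log2 change 10.23 ± 1.09), CXCL8 (9.47 ± 1.37) and CXCL1 (9.23 ± 1.21) rose, together with IL6 (9.47 ± 1.12) and the interferon-induced chemokine CXCL10 (9.25 ± 1.14), each in 3 of 3 donors. Basal CXCL8 averaged 3.41, within the range of the array medians, so changes from such levels were compressed and the order of these genes was not measured. Among the inflammatory cytokines and chemokines, 21 of 22 tested members rose (22 when adjusted over the list alone), including CCL20 (7.94 ± 1.20), CCL8 (7.64 ± 0.97) and IL1B itself (6.72 ± 0.75). Of the NF-kB feedback and adhesion genes, 11 of 12 rose (11 adjusted over the list alone), among them TNFAIP3 (7.43 ± 0.84), a deubiquitinase that restrains NF-kB, its inhibitor NFKBIA (4.26 ± 0.53) and NFKB1 (2.53 ± 0.37). Interferon-stimulated genes rose in 26 of 29 cases (29 adjusted over the list alone), with MX1 (8.22 ± 1.23), ISG20 (5.92 ± 0.59), IFIT2 (4.71 ± 0.46) and the peptide transporter TAP1 (3.65 ± 0.39). CXCL10 and CXCL11 stand in both this list and the cytokine list. All 3 lists passed camera, with adjusted p = 0.000462 (interferon), 0.000735 (cytokines) and 0.00437 (NF-kB) with an estimated correlation.

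Among the enzymes of prostaglandin E2 synthesis, those that rose were the phospholipase PLA2G4A (3.62 ± 0.61), the inducible cyclooxygenase PTGS2 (7.56 ± 1.05, from a mean of 3.83 ± 1.09 (SD, n = 4) to 11.39 ± 0.70 (SD, n = 3)) and the synthase PTGES (4.83 ± 0.54), the 3 members called of the 15 tested in the prostanoid list (4 adjusted over the list alone; camera adjusted p = 0.0053 with an estimated correlation). The bradykinin receptors BDKRB1 (4.42 ± 0.96) and BDKRB2 (2.20 ± 0.61) rose as well. Of the glycolysis genes, 10 of 19 rose (11 higher and 1 lower adjusted over the list alone), including hexokinase HK2 (2.55 ± 0.39), PFKFB3 (2.82 ± 0.49), the glucose transporter SLC2A1 (2.71 ± 0.51) and ENO1 (0.96 ± 0.16), with camera adjusted p = 0.0705 with an estimated correlation. GCH1, the first enzyme of tetrahydrobiopterin synthesis, rose by 7.75 ± 1.11. Of the cAMP and CREB target genes 7 of 16 rose (8 higher and 1 lower adjusted over the list alone), among them DUSP1 (1.84 ± 0.22), NR4A3 (4.16 ± 0.69) and NR4A2 (3.02 ± 0.87). CREM was -0.35 ± 0.38 (adjusted p = 0.725), and the list's camera adjusted p was 0.0866 with an estimated correlation. DUSP1, PER1 and RGS2 stand in both this list and the list of glucocorticoid-induced genes counted below.

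The genes that fell with IL-1beta included TSC22D3, also called GILZ, a glucocorticoid-induced leucine zipper protein (-3.55 ± 0.63), the cell cycle inhibitor CDKN1C (-3.12 ± 0.50), the transcription factors OSR2 (-3.11 ± 0.73) and MAF (-2.98 ± 0.57), the alcohol dehydrogenase ADH1B (-3.21 ± 0.72) and monoamine oxidase MAOA (-2.69 ± 0.65). The glucocorticoid-induced list went both ways, with 7 members higher and 3 lower of 20 (8 and 3 adjusted over the list alone). Its higher members included the metallothioneins MT2A (2.02 ± 0.29) and MT1E (2.42 ± 0.38) and CRISPLD2 (2.64 ± 0.40). Of 15 cell cycle genes 2 fell, PCNA (-1.17 ± 0.33) and MCM2 (-1.14 ± 0.37), and none rose (0 higher and 4 lower adjusted over the list alone). In all, limma called 367 genes higher and 198 lower, and 669 and 709 with donor as a block. The total of 565 became 259 in a fit on the compared groups alone, and 341 and 363 without replicate 2 or 3.

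EGF acted on a smaller set, led by genes of the growth factor and ERK response. Of that list, 10 of 24 tested members rose and none fell (18 and 0 adjusted over the list alone). They included the ERK phosphatase DUSP6 (3.81 ± 0.42), the feedback inhibitor SPRY2 (2.74 ± 0.48), the AP-1 subunit FOSL1 (3.26 ± 0.75), HMGA2 (3.19 ± 0.60), EGR3 (1.75 ± 0.31) and the cytokine LIF (3.02 ± 0.79), each higher in 4 of 4 donors (camera adjusted p = 0.000645 with an estimated correlation). Glycolysis genes rose in 7 of 19 cases (12 adjusted over the list alone), with HK2 (1.94 ± 0.36), PFKP (1.43 ± 0.31), ENO1 (0.89 ± 0.15) and PGAM1 (0.69 ± 0.13). With donor as a block 14 glycolysis genes were higher and 1 lower. The list's camera adjusted p was 0.0105 with an estimated correlation. The phosphate transporter SLC20A1 (2.68 ± 0.31), sphingosine kinase SPHK1 (2.82 ± 0.58) and the prostaglandin E2 receptor PTGER4 (2.09 ± 0.55) rose too. Among the genes that fell were the clock repressor NR1D2 (-3.60 ± 0.65), DEPP1 (-3.39 ± 0.68), the BMP pseudoreceptor BAMBI (-3.05 ± 0.48), the ephrin EFNB2 (-2.91 ± 0.46) and CDKN1C (-2.82 ± 0.46). Of the 15 cell cycle genes, PCNA fell (-1.30 ± 0.30) and none rose.

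The inflammatory genes did not pass with EGF as a group with an estimated correlation (camera adjusted p = 0.456), and LIF was the 1 of 22 called over all genes (3 adjusted over the list alone). IL6 was 3.31 ± 1.04, higher in 4 of 4 donors (adjusted p = 0.0948, and 0.0116 with donor as a block), CXCL8 2.01 ± 1.26 (adjusted p = 0.65) and PTGS2 1.46 ± 0.98 (adjusted p = 0.685). CXCL8 was high in 1 donor alone. On the GFP EGF array of replicate 3 CXCL8 was 11.19, against 3.369 to 3.595 on the arrays of the other 3 donors, while IL6 was 11.76, against 5.757 to 6.711. Of interferon-stimulated genes, ISG20 alone was called (2.69 ± 0.55). The total was 94 higher and 59 lower, and 334 and 364 with donor as a block. The 153 calls became 0 in a fit on the compared groups alone (821 genes had an unadjusted p under 0.05 in the fit to all arrays), 86, 23 and 87 without replicates 1, 3 or 4, and 59 without the 4 EGF arrays of replicate 3.

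Given together, EGF and IL-1beta changed more genes than either alone against the same basal arrays. The cytokine list rose in 19 of 22 members (19 adjusted over the list alone; camera adjusted p = 0.00202 with an estimated correlation), among them CXCL2 (10.33 ± 1.00), CXCL3 (10.23 ± 0.99), CXCL8 (10.18 ± 1.26), IL6 (9.84 ± 1.04) and IL1B (8.32 ± 0.69), each in 4 of 4 donors. All 12 NF-kB feedback and adhesion genes rose (12 adjusted over the list alone; camera adjusted p = 0.0053 with an estimated correlation), and 14 of 24 ERK response genes rose with 1 lower (16 and 1 adjusted over the list alone; camera adjusted p = 0.0153 with an estimated correlation), including HBEGF (4.52 ± 0.54) and LIF (5.93 ± 0.79). PTGS2 (7.64 ± 0.98), PTGES (4.08 ± 0.50) and PLA2G4A (2.65 ± 0.57) rose, as did IL11, a cytokine of stromal cells (6.35 ± 0.76), the collagenase MMP1 (4.96 ± 1.08) and the stromelysin MMP3 (6.47 ± 1.15). Glycolysis genes rose in 12 of 19 cases (12 higher and 1 lower adjusted over the list alone), HK2 by 3.01 ± 0.36 (camera adjusted p = 0.0546 with an estimated correlation). DUSP1 rose by 2.84 ± 0.20 and NR4A2 by 3.85 ± 0.80, among 10 of 16 cAMP and CREB target genes (10 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.0563 with an estimated correlation). Interferon-stimulated genes rose in 11 of 29 cases (13 adjusted over the list alone; camera adjusted p = 0.189 with an estimated correlation), CXCL10 by 6.54 ± 1.05.

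Downward, the joint stimulus took DEPP1 by -5.84 ± 0.68, OSR2 by -5.01 ± 0.68, the growth factor FGF9 by -4.45 ± 1.16, MAF by -4.21 ± 0.52 and EFNB2 by -3.87 ± 0.46. PCNA fell by 2.07 (SE 0.30), and the fibroblast markers FAP (-1.56 ± 0.49) and PDGFRB (-1.07 ± 0.36) fell, the only 2 called of 7 (3 lower adjusted over the list alone). The stress genes went both ways, with 2 higher and 3 lower of 19 (3 and 4 adjusted over the list alone; camera adjusted p = 0.998 with an estimated correlation): DDIT3 (-1.95 ± 0.38) and ATF4 (-0.68 ± 0.13) fell, while XBP1 (1.09) and CEBPB (0.98) rose. The contractile gene LMOD1 fell (-2.73 ± 0.78) and SMTN rose (1.86 ± 0.55), the only 2 called of the 17 in that list (1 and 1 adjusted over the list alone). With donor as a block 1 contractile gene was higher and 4 were lower. The glucocorticoid receptor NR3C1 was -1.63 ± 0.82 (adjusted p = 0.198, and 0.00369 with donor as a block). Donor 1 had the largest fall, from 10.43 in basal cells to 6.06, while the other donors read 8.26 to 10.47 with both stimuli. Altogether 536 genes were higher and 585 lower, or 958 and 1590 with donor as a block, and the total of 1121 became 545 in a fit on the compared groups alone and 537 without replicate 3.

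**Figure D2:**
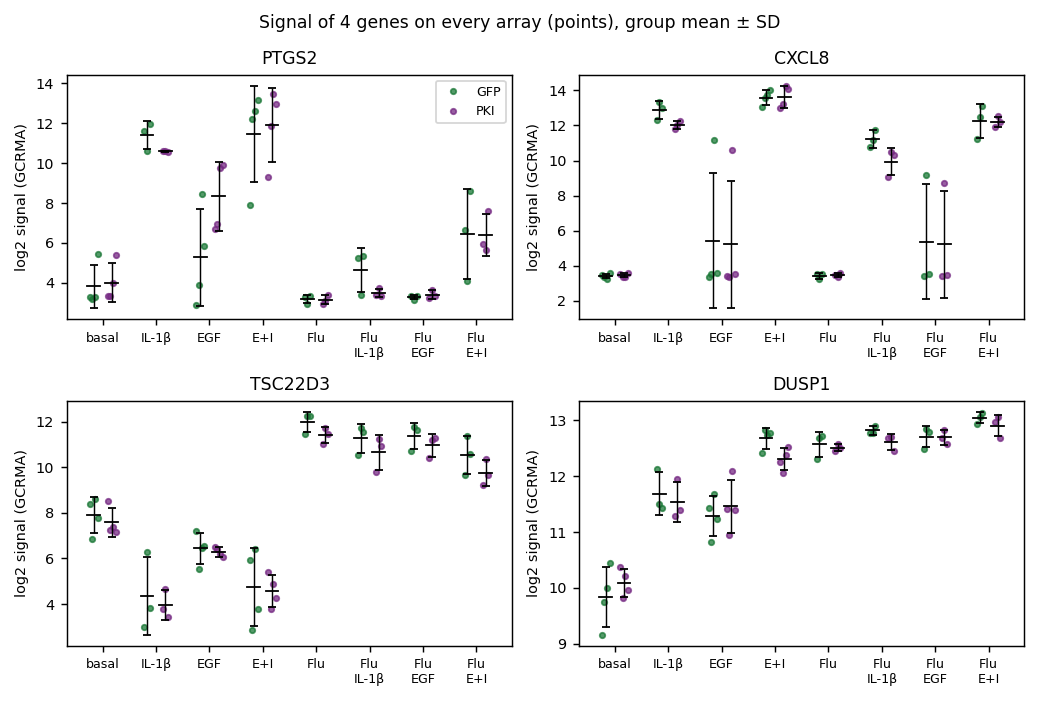
Log2 signal of PTGS2, CXCL8, TSC22D3 and DUSP1 on each array (points), with the group mean and SD, for GFP and PKI cells under 8 treatments (E+I, EGF with IL-1beta; Flu, fluticasone). PTGS2 averages 11.39 with IL-1beta and 4.66 with fluticasone added, and 1 EGF array in each of 4 groups shows high CXCL8.

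A test of non-additivity asked whether the joint response departed from the sum of the single responses on the log2 scale. Interferon-stimulated genes did: the list median was -2.31, all 29 members lay below 0 and camera gave an adjusted p of 0.00175 with an estimated correlation. Singly, limma called IFIT2 (-3.94 ± 0.63, adjusted p = 0.00152), and 13 members were called when adjusted over the list alone. On average over the list, the signal was 4.29 ± 0.24 (SD, n = 4) in basal cells, 8.64 ± 0.99 (SD, n = 3) with IL-1beta, 4.23 ± 0.26 (SD, n = 4) with EGF and 6.15 ± 1.57 (SD, n = 4) with both. The prostanoid list also passed (median -0.32, camera adjusted p = 0.01 with an estimated correlation), with none of 15 members called over all genes (1 lower adjusted over the list alone) and PTGER4 at -2.58 ± 0.81 (adjusted p = 0.592, and 0.0132 with donor as a block). Without the EGF arrays of replicate 3, a fit chosen after seeing the data, its median was -0.46 and its adjusted p over the 19 lists was 0.0148 with an estimated correlation. The prostanoid list was not tested without donor 1, which has no array with IL-1beta alone. With both stimuli PTGS2 was 7.89 in GFP cells of donor 1, against 12.2 to 13.13 in the other donors. Glycolysis (median -0.58), ERK response (-0.86), cytokine (-1.16) and cell cycle genes (0.25) passed only with the preset correlation (adjusted p = 0.0604, 0.114, 0.622 and 0.452 with an estimated correlation), and without those EGF arrays the cytokine median was -0.14 (adjusted p = 0.348 with the preset). PTGS2 was -1.39 ± 1.44, IL6 -2.95 ± 1.52 and CXCL8 -1.31 ± 1.86, none past the threshold.

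Limma called 0 genes higher and 1 lower for non-additivity (243 at an unadjusted p under 0.05), and 3 and 10 with donor as a block. The change of IFIT2 stayed between -4.57 and -3.55 when any donor was left out, but its call was lost without replicate 1, 3 or 4 (adjusted p = 0.0578, 0.47 and 0.227) and in a fit on the compared groups alone (the change was -3.94 as in the fit to all arrays, adjusted p = 0.388), and the stricter filter left the gene out of the test, with a count of 0. Without replicate 2 the count was 8. Donor 1 has no array with IL-1beta alone, and without it the median of the interferon-stimulated genes was -1.67, with 29 of 29 below 0.

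**Figure D3:**
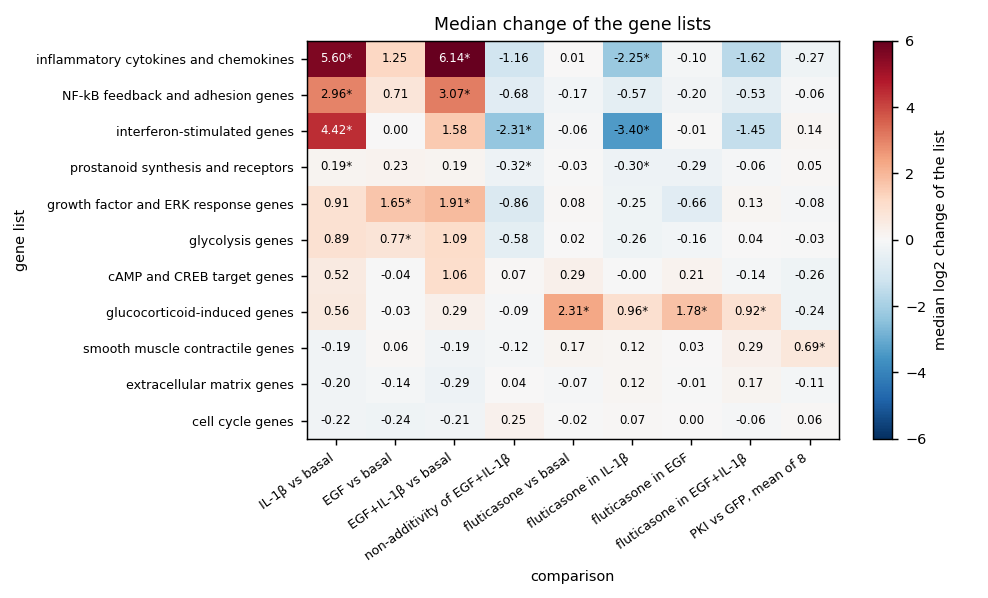
Median log2 change of 11 gene lists (rows) in 9 comparisons (columns), printed in each cell; an asterisk marks camera with an estimated correlation past an adjusted p of 0.05. Interferon-stimulated genes have a median of 4.42 with IL-1beta and -3.40 when fluticasone is added to it.

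Fluticasone alone raised the classical targets of the glucocorticoid receptor. Of the list of glucocorticoid-induced genes, 12 of 20 tested members rose and none fell (15 and 0 adjusted over the list alone; camera adjusted p = 4.45e-12 with an estimated correlation). ZBTB16 rose by 4.81 ± 0.52, TSC22D3 by 4.08 ± 0.63, CRISPLD2 by 3.95 ± 0.40, the receptor's co-chaperone FKBP5 by 3.34 ± 0.47 (from a mean of 2.65, below the array medians, so the change was compressed), the MAP kinase phosphatase DUSP1 by 2.73 ± 0.22 and glutamine synthetase GLUL by 2.65 ± 0.35. Outside that list, the metallothionein MT1M (5.94 ± 0.90), FAM107A (5.81 ± 0.53), TIPARP (4.75 ± 0.58), FOXO1 (3.19 ± 0.56) and NFKBIA (2.46 ± 0.53) rose, and of the contractile genes VCL, vinculin, did (1.82 ± 0.25). FOS (3.03 ± 0.43) and NFIL3 (2.13 ± 0.33) rose with DUSP1 as 3 of 16 cAMP and CREB target genes (3 adjusted over the list alone; camera adjusted p = 0.0563 with an estimated correlation). DUSP1 is thus counted in both lists.

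The genes lowered by fluticasone alone included osteoprotegerin, TNFRSF11B (-4.65 ± 0.81), the hyaluronan-binding TNFAIP6 (-4.09 ± 0.74), both bradykinin receptors BDKRB1 (-3.81 ± 0.96) and BDKRB2 (-3.75 ± 0.61), the early response gene IER3 (-3.78 ± 0.76) and the amino acid transporter SLC7A5 (-2.85 ± 0.52). TRIB3 (-2.27 ± 0.55) and DDIT3 (-1.60 ± 0.41) were the 2 of 19 stress genes that fell (4 adjusted over the list alone; camera adjusted p = 0.0619 with an estimated correlation). NR3C1 was -1.76 ± 0.89 (adjusted p = 0.688, and 0.00195 with donor as a block), lower in 3 of 3 donors. Limma called 92 genes higher and 33 lower, or 258 and 119 with donor as a block. The total of 125 became 36 in a fit on the compared groups alone and 51 without replicate 3.

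On top of IL-1beta, fluticasone took down the antiviral-type genes and part of the inflammatory set. Interferon-stimulated genes fell in 16 of 29 cases (27 adjusted over the list alone; camera adjusted p = 5.85e-05 with an estimated correlation). MX2 fell by 6.42 (SE 1.13), IFIT1 by 6.35 (SE 1.29), MX1 by 6.26 (SE 1.31) and IFIT3 by 5.54 (SE 0.86), and the list's mean signal was 5.03 ± 0.36 (SD, n = 3) against 8.64 ± 0.99 with IL-1beta alone. Of the cytokines 7 of 22 fell (11 adjusted over the list alone; camera adjusted p = 0.0231 with an estimated correlation, and 0.061 with donor as a block), including CCL8 (-6.95 ± 1.04), CCL7 (-5.60 ± 1.09) and IL1B (-5.52 ± 0.80). IL6 was -2.90 ± 1.20 (adjusted p = 0.363) and CXCL8 -1.65 ± 1.46 (adjusted p = 1), both lower in 3 of 3 donors. The SE of IL6 and CXCL8 rested on the spread shared by all 16 groups. That spread was widest in the 4 EGF groups (SD of CXCL8 3.06 to 3.85, of IL6 2.22 to 3.5). IL6 averaged 13.87 ± 0.03 (SD, n = 3) with IL-1beta and 10.97 ± 0.34 (SD, n = 3) with fluticasone added. CXCL8 averaged 12.88 ± 0.53 and 11.24 ± 0.51. The missing calls therefore do not show that fluticasone left these genes unchanged. The same 3 prostanoid enzymes fell, PTGS2 by 6.73 (SE 1.13), PLA2G4A by 3.62 (SE 0.65) and PTGES by 2.38 (SE 0.58), the 3 called of 15 (3 adjusted over the list alone). Of the 12 NF-kB feedback and adhesion genes none passed over all genes, and 1 did when adjusted over the list alone.

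Glucocorticoid-induced genes rose in 7 of 20 cases in the presence of IL-1beta (10 adjusted over the list alone; camera adjusted p = 2.29e-07 with an estimated correlation), with TSC22D3 at 6.91 ± 0.68, ZBTB16 at 5.31 ± 0.55 and FKBP5 at 3.09 ± 0.50. FAM107A (6.25 ± 0.57), DEPP1 (5.12 ± 0.79), MAOA (3.68 ± 0.69) and the matricellular gene CCN2 (3.42 ± 0.70) rose too. DUSP1 rose by 1.13 ± 0.24 from an already raised level, and NR4A3 fell (-3.67 ± 0.74). LIF (-4.76 ± 0.92), BHLHE40 (-4.07 ± 0.70), IL11 (-3.33 ± 0.88) and ID2 (-3.15 ± 0.60) fell. Their lists went both ways, with 1 higher and 3 lower of 24 ERK response genes (1 and 5 adjusted over the list alone) and 1 higher and 4 lower of 17 TGF-beta response genes (1 and 4 adjusted over the list alone), and neither passed with an estimated correlation (adjusted p = 0.737 and 0.48). The totals were 67 higher and 98 lower, or 190 and 241 with donor as a block. The 165 calls became 40 in a fit on the compared groups alone and 109, 75 and 94 without replicates 2, 3 or 4.

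In cells given EGF, fluticasone again raised 12 of 20 glucocorticoid-induced genes and lowered none (14 and 0 adjusted over the list alone; camera adjusted p = 2.87e-11 with an estimated correlation). ZBTB16 rose by 5.43 ± 0.52, TSC22D3 by 4.93 ± 0.63, CRISPLD2 by 3.09 ± 0.40 and DUSP1 by 1.42 ± 0.22. DEPP1, which EGF lowered, rose by 4.96 ± 0.74, and the ERK inhibitor SPRY1 rose by 2.07 ± 0.38. BDKRB1 (-3.68 ± 0.96), BDKRB2 (-3.37 ± 0.61), LIF (-3.63 ± 0.86), IER3 (-3.56 ± 0.76), EGR3 (-1.28 ± 0.34) and the cartilage regulator SOX9 (-2.31 ± 0.52) fell. The 2 bradykinin receptors were the called members of a receptor and PKA subunit list of 17 (2 lower adjusted over the list alone; camera adjusted p = 0.0463 with an estimated correlation). The ERK response list as a whole went both ways, with 1 member higher and 3 lower of 24 (2 and 6 adjusted over the list alone, 2 and 7 with donor as a block; camera adjusted p = 0.561 with an estimated correlation). Limma called 58 genes higher and 36 lower, or 154 and 136 with donor as a block, and the total of 94 became 9 in a fit on the compared groups alone and 47 and 54 without replicates 3 or 4.

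With both stimuli present, fluticasone lowered the anti-apoptotic BCL2A1 (-6.01 ± 0.58), IL11 (-5.51 ± 0.82), PTGS2 (-5.02 ± 1.05), MMP1 (-4.83 ± 1.17), IL33 (-4.65 ± 0.96), the EGF receptor ligand HBEGF (-4.51 ± 0.58) and BMP2 (-4.51 ± 0.84), each in 3 of 3 donors. Only the arrays without fluticasone include donor 1, so these changes also compare donors. In GFP cells of donor 1 with both stimuli PTGS2 was 7.89 and NR4A2 3.39, against 12.2 to 13.13 and 7.90 to 9.31 in the others. This made the falls of PTGS2 and NR4A2 look smaller. In donors 2, 3 and 4 PTGS2 went from 12.2 to 6.65, from 12.62 to 4.09 and from 13.13 to 8.58. Of the cytokines 6 of 22 fell (7 adjusted over the list alone; camera adjusted p = 0.0732 with an estimated correlation), including IL1B (-3.55 ± 0.75) and IL1A (-2.28 ± 0.43). IL6 was -2.34 ± 1.12 and CXCL8 -1.33 ± 1.37, neither called, with SE that again hold the spread of the EGF groups. IL6 averaged 14.24 ± 0.52 (SD, n = 4) without and 11.91 ± 0.59 (SD, n = 3) with fluticasone. CXCL8 averaged 13.59 ± 0.41 and 12.26 ± 0.97. Among cAMP and CREB target genes 4 of 16 fell, the orphan receptors NR4A2 (-3.86 ± 0.87) and NR4A3 (-2.69 ± 0.69), the kinase SIK1 (-1.85 ± 0.45) and the small GTPase GEM (-1.90 ± 0.37), with 1 higher and 7 lower when adjusted over the list alone (camera adjusted p = 0.0604 with an estimated correlation). CREM was -1.38 ± 0.38 (adjusted p = 0.0535, and 0.0358 with donor as a block). Of interferon-stimulated genes 1 of 29 fell, ISG20 (-2.49 ± 0.59), and 6 when adjusted over the list alone (camera adjusted p = 0.0604 with an estimated correlation). The signaling adaptor TRAF1 fell by 3.12 (SE 0.40).

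DEPP1 rose (7.62 ± 0.74), with TSC22D3 (5.80 ± 0.63), FAM107A (4.79 ± 0.53) and ZBTB16 (4.76 ± 0.52). Of the glucocorticoid-induced genes 5 of 20 rose (10 adjusted over the list alone; camera adjusted p = 3.51e-06 with an estimated correlation), FKBP5 by 1.92 ± 0.47, while DUSP1 was 0.37 ± 0.22 (adjusted p = 0.96). CCN2 (3.47 ± 0.65), CCN4 (3.37 ± 0.75) and vinculin VCL (1.49 ± 0.25) rose, and of 22 extracellular matrix genes COL4A1 alone did (1.36 ± 0.29; 1 adjusted over the list alone; camera adjusted p = 0.996 with an estimated correlation). The counts were 68 higher and 49 lower, or 186 and 120 with donor as a block. The total of 117 became 25 in a fit on the compared groups alone and 38 without replicate 3.

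Overlaps were counted to ask whether the genes raised by IL-1beta were those lowered by fluticasone in cells given both stimuli, in contrasts that share no array. Of the 367 genes raised and the 49 lowered, 25 were the same, against 2.34 for independent lists. They included BCL2A1, IL11, PTGS2, IL33, BMP2, CCL8, NR4A2, LIF, IL1B, PLA2G4A and IL1A. Another 4 of the raised genes were raised further by fluticasone. With donor as a block the overlap was 60, against 10.4 for independent lists, and it was 15 with the stricter filter, 3 in fits on the compared groups alone, and 11, 8 and 10 without replicates 2, 3 or 4. Among the 325 genes that IL-1beta raised at least 2-fold, the median change with fluticasone was -0.42 in cells given both stimuli, and 244 lay below 0. With fluticasone in EGF cells 211 did (median -0.15). With fluticasone alone, which shares the basal arrays, 139 did (median 0.03). For PKI against GFP the numbers were 184 with both stimuli (median -0.10) and 202 with EGF (median -0.06).

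IL-1beta and EGF raised 49 genes in common of 367 and 94, against 4.48 for independent lists. Both contrasts share the 4 basal GFP arrays. With these split 2 and 2 in each of 6 ways, the overlap ranged from 6 to 25, against 0.788 to 2.77 for independent lists. With donor as a block it was 159 (29 for independent lists), without the EGF arrays of replicate 3 it was 22, in fits on the compared groups alone it was 0, and it was 21, 6 and 23 without replicates 1, 3 or 4.

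PKI was compared with GFP to ask what inhibiting PKA did to each state. The PKIA probe set read 4.58 ± 0.87 in GFP and 4.84 ± 0.99 in PKI cells (SD, n = 27 arrays each); where it lies relative to the expressed inhibitor sequence is not given in the sources used here, so it checks no label. Averaged over the 8 conditions, PKI cells had higher levels of contractile genes. Of 17 tested members 10 rose and none fell (12 and 0 adjusted over the list alone; camera adjusted p = 0.00145 with an estimated correlation), with a median of 0.69. Without replicate 3 the members called were 5 and the median 0.41, and the medians of the single donors ran from 0.16 to 0.94. The p-values and SE of these PKI comparisons treat arrays from the same transduced cells of a donor as independent. Transgelin TAGLN was 1.40 ± 0.18, higher in 2 of the 3 donors with all conditions, the myosin light chain MYL9 1.34 ± 0.14, and the tropomyosins TPM1 and TPM2 were 1.03 ± 0.16 and 0.69 ± 0.09. The list's mean signal was 8.36 ± 0.49 in GFP and 9.15 ± 0.11 in PKI basal cells (SD, n = 4 each). The list passed with the preset correlation in each of the 4 conditions without fluticasone, the only ones in which single conditions were compared; with an estimated correlation its adjusted p was 0.0546 in basal and EGF cells, 0.00664 with IL-1beta (0.0552 with donor as a block) and 0.00448 with both stimuli, although none of its members was called there over all genes (5, 4, 6 and 8 higher in these conditions adjusted over the list alone). The GAPDH 3'/5' log2 ratio was lower in PKI arrays than in their GFP partners in 11 of 27 pairs (mean difference -0.0276, SD 0.161, n = 27). The actin 3'/5' log2 ratio was lower in 25 of 27 pairs (mean difference -0.374, SD 0.371, n = 27). The means of the 4 donors were all lower (mean -0.318, SD 0.24; exact permutation test over sign changes of the donors, two-sided, p = 0.125, the smallest it can give).

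**Figure D4:**
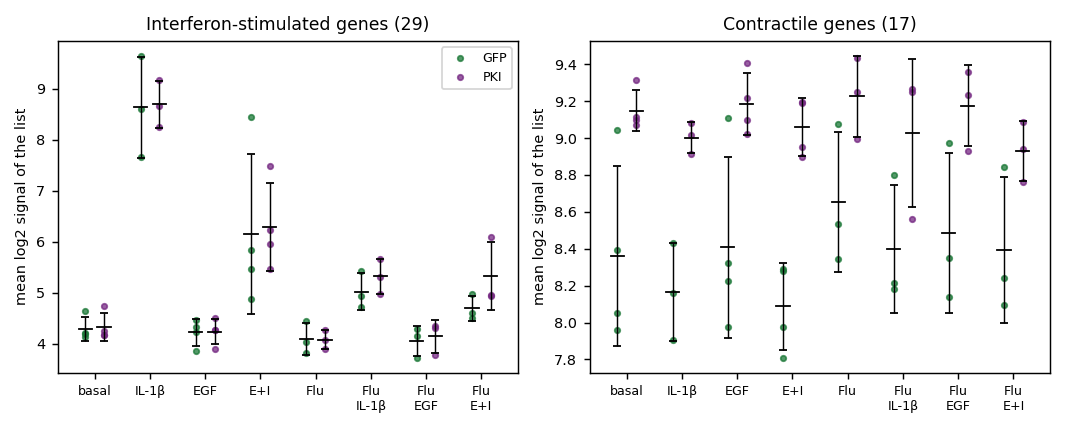
Mean log2 signal of 29 interferon-stimulated genes (left) and 17 contractile genes (right) on each array (points), with group mean and SD, for GFP and PKI cells under 8 treatments. Contractile genes average 8.36 in GFP and 9.15 in PKI basal cells, and interferon-stimulated genes average 8.64 with IL-1beta and 6.15 with EGF added in GFP cells.

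Other genes higher with PKI on average were the hedgehog receptor PTCH1 (2.11 ± 0.17), the calcium-activated chloride channel ANO1 (1.80 ± 0.14), WFDC1 (2.54 ± 0.45), the G-protein signaling regulators RGS4 (1.57 ± 0.40) and RGS5 (1.48 ± 0.29), TGFBI (0.70 ± 0.08) and the surface marker THY1 (0.77 ± 0.11). Lower were periplakin PPL (-2.46 ± 0.32), CSGALNACT1, an enzyme of chondroitin sulfate synthesis (-1.74 ± 0.21), SEMA3C (-1.71 ± 0.25), the prostaglandin F receptor PTGFR (-1.48 ± 0.38), AVPI1 (-1.48 ± 0.18), complement factor CFB (-1.42 ± 0.26), ID2 (-1.02 ± 0.20), the cytokine IL33 (-1.22 ± 0.34) and the IL-1 receptor IL1R1 (-0.68 ± 0.18). The collagens COL3A1 (-0.48 ± 0.09) and COL5A1 (-0.51 ± 0.14) fell, the 2 called of 22 matrix genes (3 lower adjusted over the list alone, 8 with donor as a block; camera adjusted p = 0.708 with an estimated correlation). Of 16 cAMP and CREB target genes, 2 fell and none rose, NFIL3 (-0.43 ± 0.12) and CEBPB (-0.29 ± 0.09), with 1 higher and 5 lower when adjusted over the list alone and a median of -0.26 (camera adjusted p = 0.189 with an estimated correlation). PTGS2 (0.22 ± 0.38), IL6 (-0.51 ± 0.40), CREM (-0.26 ± 0.14) and NR4A2 (-0.47 ± 0.31) were not called. The average pools states in which such genes were near background with states in which they were induced. With both stimuli NR4A2 averaged 7.20 ± 2.61 in GFP and 5.20 ± 2.15 in PKI cells (SD, n = 4 each). IL6 averaged 14.24 ± 0.52 and 13.52 ± 0.62 there, but 4.40 and 4.71 in basal cells. The missing calls therefore do not show that PKI left these genes unchanged.

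Limma called 243 genes higher and 231 lower with PKI over the 8 conditions, or 863 and 826 with donor as a block, and the total of 474 became 186 and 226 without replicates 3 or 4. With the actin ratio as a covariate 252 were higher and 372 lower, and 338 of the 474 stayed called. The arrays of a donor's transduced cells are not independent, and with 1 value per donor limma called 0 genes (1339 at an unadjusted p under 0.05), so the counts measure the spread among arrays.

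Within the 4 single conditions compared few genes passed. In basal cells 5 were higher, PTCH1 (3.63 ± 0.44), ANO1 (2.71 ± 0.36), PREB (2.54 ± 0.51), CRISPLD2 (2.14 ± 0.37) and CPM (2.05 ± 0.46), and 5 lower, DAAM1 (-2.26 ± 0.43), PTX3 (-1.60 ± 0.33), SMC4 (-1.38 ± 0.31), CUTC (-1.16 ± 0.19) and ARHGAP5 (-0.83 ± 0.18). The change of CPM (adjusted p = 0.0495) held for 1 of its probe sets, and the other, nearly as bright, changed by 0.04. CPM was -0.01 without replicate 4, where that other probe set was the brighter one, and it was not called without replicate 2 or 3 (adjusted p = 0.139 and 0.965) or with the mean of its probe sets (adjusted p = 0.114). With IL-1beta 1 gene passed, PTCH1 (3.18 ± 0.51). With EGF 7 were higher, among them PTCH1 (2.70 ± 0.44), CNIH3 (2.61 ± 0.48), NEDD9 (2.61 ± 0.57), ANO1 (1.81 ± 0.36), CRISPLD2 (1.80 ± 0.37) and MYL6 (0.66 ± 0.14). With both stimuli 8 were higher, including the potassium channel KCNJ2 (3.27 ± 0.62), CNIH3 (3.22 ± 0.48), MEOX1 (2.61 ± 0.49), ANO1 (2.06 ± 0.36) and C3orf52 (2.05 ± 0.22), and AVPI1 (-3.13 ± 0.47) and TSC22D1 (-1.07 ± 0.24) were lower. PTGS2 was 3.05 ± 0.98 higher in PKI cells with EGF (adjusted p = 0.442, and 0.0193 with donor as a block). IL33 was -2.70 ± 1.02 with IL-1beta and -2.36 ± 0.89 with EGF, neither called.

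With donor as a block the single-condition counts were 102 higher and 58 lower in basal cells, 20 and 7 with IL-1beta, 97 and 54 with EGF, and 85 and 51 with both stimuli. Without the array that matched another donor, the blocked EGF counts were 36 and 15. In fits on the compared groups alone all 4 counts were 0, and leaving out 1 donor gave 2 to 24 calls in basal cells, 0 to 14 with IL-1beta, 2 to 10 with EGF and 2 to 16 with both stimuli.

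Tests of interaction asked whether PKI changed a response. For IL-1beta limma called 0 genes (56 at an unadjusted p under 0.05, and 0 with donor as a block), with IL1B at -1.98 ± 1.06. For EGF it called 0 (407 unadjusted, and 0 with donor as a block), with PTGS2 at 2.85 ± 1.38 and MMP1 at 3.90 ± 1.53. For both stimuli 1 gene was called, C3orf52 (2.03 ± 0.30, adjusted p = 0.000359), higher in 4 of 4 donors, and 2 higher and 2 lower with donor as a block. Its change was 1.80 without replicate 3 (adjusted p = 0.0629) and 2.03 in a fit on the compared groups alone (adjusted p = 0.0598), and the stricter filter left it out of the test. The cAMP and CREB target list was lower for IL-1beta (median -0.42), with camera adjusted p = 0.003 with the preset and 0.189 with an estimated correlation, and PDE4D, a cAMP phosphodiesterase, was -2.15 ± 0.91. The effect of fluticasone differed between PKI and GFP cells for 0 genes with both stimuli (55 unadjusted) and for 0 genes on average over 4 conditions (129 unadjusted), and for 0 higher and 3 lower in either with donor as a block. The glucocorticoid-induced list had a median of -0.24 for the averaged difference, with none of its 20 members called (2 lower adjusted over the list alone; camera adjusted p = 0.00963 with an estimated correlation, and 0.053 with donor as a block), and ZBTB16 was -1.53 ± 0.37 (adjusted p = 0.465). Genes both raised by IL-1beta and lowered by PKI in cells given both stimuli numbered 0, against 0.0954 for independent lists (9 against 4.44 with donor as a block). Genes lowered by both fluticasone and PKI there numbered 1, against 0.0127, and 11 against 0.796 with donor as a block; with the 4 shared arrays split 2 and 2 the count was 0 or 1.

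Markers of other cell types were also measured. None of 8 leukocyte markers passed the filter on dim probe sets, the highest being LYZ with a mean of 2.97, below the lowest array median of 3.299. Of 8 endothelial markers 2 passed (highest TEK, 4.36) and of 9 epithelial markers 4 (highest MUC1, 6.80). SOX9 (8.98) was the highest of the 4 of 8 chondrocyte markers that passed. Of 8 fibroblast markers 7 passed (highest S100A4, 13.20; lowest CD34, 2.02), as did 17 of 18 contractile genes. Levels of different probe sets were not compared.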

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

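The tests of the array that matched another donor, of an exchange of the replicate 3 arrays, of a single donor carrying the contractile shift and of dividing cells were chosen or reworded only after the result was seen, as were the splits of whole cultures for the mean PKI effect and the fits with the actin ratio and without the replicate 3 EGF arrays.

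Among 13 measures in the 6 groups of 4 arrays (78 tests for 1 array far from the other 3), 7 values stood apart, and chance gives about 1 in 20. PTGS2 was 5.459 on 1 basal GFP array, against 3.214 to 3.32. With EGF, 1 GFP array had IL6 at 11.76 (others 5.757 to 6.711) and CXCL8 at 11.19 (3.369 to 3.595), and 1 PKI array had CXCL8 at 10.63 (3.334 to 3.516). FKBP5 was 2.501 on 1 PKI EGF array, against 2.624 to 2.637, a small gap near background. In basal PKI cells TSC22D3 was 8.532 on 1 array (7.174 to 7.359) and NR4A2 was 3.449 (3.245 to 3.257).

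Responses differed between groups for IFIT2, whose change with EGF and IL-1beta together departed from the sum of the single changes by -3.941, and for C3orf52, whose response to both stimuli was 2.033 higher in PKI than in GFP cells. Neither count of 1 gene excludes chance: for non-additivity 12 of 100 permutations gave as many called genes (highest other 77), and for the interaction 14 of 35 splits did (highest other 10).

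The high CXCL8 and IL6 with EGF belonged to replicate 3 in all 4 EGF groups. Over 261 genes raised by IL-1beta in the other donors, the EGF change of replicate 3 exceeded that of the others by a median of 0.542 (GFP), 0.625 (PKI), 0.472 (GFP with fluticasone) and 0.276 (PKI with fluticasone). An exchange with the arrays given both stimuli was argued against, since those also carried the response (lowest median 0.983), and so was RNA quality, since 0 of 4 arrays lay outside the donor's other arrays on the control ratios. Exposure of these cultures to IL-1beta or to factors it induces may be a candidate source, since of 99 genes lowered by IL-1beta 72, 65, 71 and 85 were lower than in the other donors in the 4 groups (highest median excess -0.263). Interferon-stimulated genes showed less of it, with a median excess of 0.288, 0.306, 0.104 and 0.156. In GFP cells of replicate 3 their list mean was 4.129 in basal cells, 4.476 with EGF, 7.669 with IL-1beta and 5.467 with both. These genes responded less to IL-1beta when EGF was present, so their values do not decide. A response to EGF peculiar to this donor was not tested and stays open.

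The array that did not match its donor label had a mean correlation of 0.404 with another donor's arrays and 0.0485 with its own. It belonged to the same-group pair with the highest correlation of 66 (0.9865, next 0.9714). An exchange with an array of that other donor was argued against, since 0 further arrays of the 54 matched another donor best. A wrong donor label, or cells or RNA of the other donor, stays open and is consistent with the value of 0.404. No biological explanation was tested.

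The higher contractile genes of PKI cells were weighed against 3 explanations. With the actin ratio as a covariate the list median was 0.652, against 0.689 without it, which argues against the RNA signal that this ratio measures as the whole cause. With any 1 donor left out the lowest median was 0.408, although the donors ranged from 0.16 to 0.945 and an earlier bound of 0.2 for every donor was missed by 1 of them. Fewer dividing cells stay open, since the 15 cell cycle genes went both ways (median 0.0643, 5 below 0). An effect of PKA inhibition may explain the shift, but the arrays of each donor share its transduced cells, so the history of the cultures stays open.

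Over all splits of the arrays, no other split gave as many genes as the real labels for IL-1beta (565 genes, 1 of 35 splits as large, highest other 334), EGF (153, 1 of 35, 55) and both stimuli (1121, 1 of 35, 114). The same held for fluticasone alone (125, 1 of 35, 86), with EGF (94, 1 of 35, 39) and with both stimuli (117, 1 of 35, 90). The 1 split as large was the real one. Most of these splits mix arrays that donors pair, so on their own they do not exclude chance. For the mean PKI effect (474) 1 of 100 drawn splits within the conditions was as large (highest other 2), but those break up the cultures that gave all arrays. With the 8 whole cultures reassigned, 22 of 35 splits were as large (highest other 4439). Splits that leave both cultures of a donor on 1 side also compare donors, whose arrays correlate. They therefore decide little about the PKI labels, and chance was not excluded there. Of the 8 of these splits that part each donor's cultures, the real one gave the most genes (highest other 187). Chance was not excluded for PKI in basal cells (10; 4 of 35, 24), with EGF (7; 5 of 35, 98) or with both stimuli (10; 6 of 35, 203). The splits with 98 and 203 genes point to a structure of the samples. Among the 8 splits that, like the real one, part the arrays of each donor, the highest others were 1 for both, and 2 for PKI in basal cells, 141 for IL-1beta, 1 for EGF, 3 for both stimuli, and 11, 27 and 90 for fluticasone alone, with EGF and with both stimuli. These 8 are too few for a share under 0.05, so among them chance was not tested to that level. The 10 splits of 3 against 3 are too few for a share under 0.05. There the counts were 165 for fluticasone with IL-1beta (1 of 10 as large, highest other 1) and 1 for PKI with IL-1beta (6 of 10, 8). Where limma called 0 genes, every split was as large by construction, so the splits decide nothing: for PKI on the EGF response (407 at an unadjusted p under 0.05; 35 of 35, highest other 5), on the IL-1beta response (56; 10 of 10, 2), on fluticasone with both stimuli (55; 10 of 10, 2) and on fluticasone on average (129; 10 of 10, 6).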

How the results depend on the processing

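The fits without the array that matched another donor, without the EGF arrays of replicate 3, with the actin ratio and with 1 value per donor were chosen only after the result was seen. Of 350 counts compared between settings, 223 stayed within 1.5 times and 127 moved. For named genes, only the 377 pairs of gene and contrast called in the main fit were followed. Of their 5572 values in the other settings, 4884 kept their direction and side of the threshold, 687 kept their direction only, and 1 reversed. That was CPM in basal PKI cells, whose log2 change ran from -0.01113 (without replicate 4) to 2.446 (without replicate 1). Without replicate 4 another of its probe sets had the highest mean and was used; the one used otherwise still changed by 1.79.

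With donor as a block, which takes up the spread between donors, the counts were 1378 for IL-1beta, 698 for EGF, 2548 for both stimuli and 13 for non-additivity. They were 377, 431, 290 and 306 for fluticasone alone, with IL-1beta, with EGF and with both stimuli, and 160, 27, 151 and 136 for PKI in basal cells and with the same stimuli, and 1689 for the mean PKI effect. The interactions gave 4 for PKI on both stimuli and 3 each for PKI on fluticasone, with both stimuli and on average. The overlaps were 60 (IL-1beta raised, fluticasone lowered), 9 (IL-1beta raised, PKI lowered), 159 (IL-1beta and EGF raised) and 11 (fluticasone and PKI lowered).

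With the block and without the array that matched another donor, the same counts in the same order were 1463, 788, 2666 and 13, then 400, 450, 310 and 316, then 190, 37, 51, 151 and 1827, then 4, 3 and 3, and the overlaps 65, 10, 178 and 11.

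With the compared groups alone in the fit, which have fewer degrees of freedom for the spread, the counts were 259 for IL-1beta, 0 for EGF, 545 for both stimuli and 0 for non-additivity. They were 36, 40, 9 and 25 for fluticasone, and 0 for PKI in each single condition. The overlaps were 3, 0 and 0 (IL-1beta with fluticasone, IL-1beta with EGF, fluticasone with PKI), and 197 of 377 named results passed. For the limma counts of 0, the numbers at an unadjusted p under 0.05 in the fit to all arrays were 821 (EGF), 243 (non-additivity), and 465, 207, 438 and 400 (PKI in basal cells, with IL-1beta, with EGF and with both).

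The stricter filter gave 0 for non-additivity, 4 for PKI in basal cells, 5 with both stimuli, 0 for PKI on both stimuli, and 15 for the overlap of IL-1beta and fluticasone. No filter gave 3 for PKI with IL-1beta. Quantile normalization gave 2 for PKI with IL-1beta and 18 with both stimuli, and overlaps with PKI of 2 (IL-1beta) and 3 (fluticasone). The mean of a gene's probe sets gave 19 for PKI with both stimuli, 2 for PKI on both stimuli, and overlaps with PKI of 1 and 4. Without an intensity trend the overlap of fluticasone and PKI was 2. The actin ratio as a covariate gave 2 for non-additivity, 2 for PKI with IL-1beta, 25 with both stimuli and 2 for the overlap of IL-1beta and PKI. Without the EGF arrays of replicate 3, EGF gave 59, PKI with EGF 4, and the overlap of IL-1beta and EGF 22. With 1 value per donor the mean PKI effect gave 0 (1339 at an unadjusted p under 0.05 in limma). With an estimated correlation 23 of 342 list shifts passed, against 77. The cause was not tested for these changes.

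Leaving out 1 donor gave 341 to 515 for IL-1beta, 23 to 162 for EGF, 537 to 984 for both stimuli and 0 to 8 for non-additivity. Fluticasone gave 51 to 103 alone, 75 to 188 with IL-1beta, 47 to 95 with EGF and 38 to 146 with both. PKI gave 2 to 24 in basal cells, 0 to 14 with IL-1beta, 2 to 10 with EGF, 2 to 16 with both and 186 to 555 on average. The interactions gave 0 to 1 for IL-1beta, 0 to 2 for EGF, and 0 to 1 for fluticasone with both stimuli and on average. The overlaps were 8 to 28, 0 to 1, 6 to 48 and 0 to 6, and 234 to 330 named results passed. Groups then held 2 or 3 arrays, and signal near background limits what dim genes show.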

Other observations

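The test of the PKI arrays and those of replicate 3 and donor 1 below follow from a pattern seen in these data, and the fit without the EGF arrays of replicate 3 was chosen only after the result was seen.

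Interferon-stimulated genes responded less to EGF with IL-1beta than the sum of the single responses, and also less than to IL-1beta alone, with a median difference of -2.44 in GFP cells, 29 of 29 genes lower and 8 called. A candidate explanation is that EGF restrains the interferon response that IL-1beta sets off. The PKI arrays, from the same donors, gave a non-additivity median of -2.31, so the pattern appeared in both sets of cultures. Without the EGF arrays of replicate 3 the GFP median was -2.35, which argues against these arrays as its source. Without donor 1, which has no IL-1beta array, all groups held the same donors, and the median was -1.67 in GFP and -1.66 in PKI cells. Within donors 2, 3 and 4 the GFP list mean was 9.642, 7.669 and 8.6 with IL-1beta and 8.435, 5.467 and 5.838 with both. The larger -2.31 and -2.44 include donor 1, whose GFP list mean with both was 4.876. A part of that size may therefore come from the donors compared. For donor 1 itself the share of EGF could not be separated.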
